A study of Mus musculus with 2 samples.

How the data were processed

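The study measured gene expression in single cells of mouse tongue papilla organoids with the 10x Genomics 3′ v3.1 droplet chemistry. Per the labels, the organoid medium held R-spondin, Noggin, EGF and Jagged-1, among other factors. There were 2 libraries, 1 from organoids embedded in Matrigel and 1 from organoids cultured in suspension in low-attachment plates, and their groups were taken from the labels. Separate cultures or animals behind each library are not described in the labels used here.

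The authors deposited UMI counts per gene and cell, with no normalization, in 1 matrix that holds both libraries. The submitters' processing notes name Cell Ranger 3.1.0, bcl2fastq, Seurat 3 and the genome build mm10, with no role or order given, per the submitters' processing notes. The annotation, the cell filters and any cell type annotation by the authors are not given in the sources used here. All values were whole numbers. The matrix held 47729 gene symbols, of which 25947 had a UMI. Barcodes ranged from 501 to 7490 detected genes and up to 9.99% mitochondrial UMIs, so the deposited counts look filtered for cells at 500 genes and 10% mitochondrial UMIs before deposit. Shallow cells and cells with high mitochondrial content are therefore missing from both libraries. UMI counting collapses amplification copies, but RNA free in the cell suspension still adds UMIs to cells that do not express a gene.

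From the deposited counts, cells with at least 500 genes and at most 20% mitochondrial UMIs were kept, which removed no barcode. Scrublet, run per library through scanpy 1.11.5, called 1 of 10041 and 0 of 12030 barcodes doublets. That is under 0.5%, the smallest share taken here as a working call. Whether the caller failed or doublets had been removed before deposit is not known. No doublets beyond that 1 barcode were removed here. Removing the 8% of cells with the highest doublet score was added as an alternative. Counts were summed over the kept cells of each library, divided by the total and multiplied to CPM. Each log2 ratio is suspension over Matrigel, with an exact conditional binomial 95% interval. CPM values have exact Poisson intervals and shares exact Clopper-Pearson intervals, and all of these cover counting error only. With 1 library per culture no test, p-value or count of changed genes was computed. Factors of the trimmed mean of M values from edgeR 4.0.16 and median-of-ratios factors from DESeq2 1.42.0, in R 4.3.3, were used for scaling alternatives only.

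Gene lists were compared through the median log2 ratio of members with at least 50 UMIs in both libraries together. Its percentile was taken among 10000 random lists of the same size drawn from 20 bins of mean expression, and members were counted as higher or lower at 1.5-fold. The percentile describes these libraries and is not a test.

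Cells of both libraries were clustered together on log-normalised counts with 2000 variable genes chosen within each library, 30 principal components, 15 neighbours and the Leiden algorithm at resolution 0.8 (igraph 0.11.9, scikit-learn 1.9.0). Clusters were named from marker lists fixed in advance when at least 3 markers of a class were raised 1.5-fold over other cells at 20 CPM or more and the 10 leading genes did not speak for another class. The marker lists were fixed in advance, but the scoring rule was written, and revised more than once, after the clusters had been seen. The CPM floor was raised from 10 to 20 in that way. The names of the main clustering are the same with both floors, while names in the alternative clusterings were not stable. Classes with at least 50 cells in each library were compared within.

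To compare shares of cells with a UMI, each cell was thinned to 3000 UMIs, and shallower cells were left out (860 and 1783 cells). Co-detection was the number of thinned cells with at least 2 markers of a taste cell type, beside the number expected if markers were detected independently in that library. Cell cycle shares counted cells with at least 3 genes of a G2M list.

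The genes to be named were chosen by a rule. They are the 12 highest and 12 lowest log2 ratios among genes with at least 50 CPM in 1 library and detected in at least 5% of its cells, without mitochondrial, ribosomal protein, haemoglobin and unnamed gene models. In each class the 5 highest and 5 lowest by the same rule were taken. Up to 4 members per fixed list or marker class with at least 10 CPM in 1 library were taken by absolute ratio, besides taste markers at any level and the 10 most abundant genes of each library. Some genes that the rule selects are not reported here. Genes named outside this rule are said to be chosen after their values were seen. The samples, rule, lists, markers and most alternatives were fixed before the data were examined.

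Gene positions are from GENCODE release M21 for mouse on GRCm38, which is mm10, matched by symbol: 45250 of the 47729 symbols (94.8%) were found. Every coordinate is the span of the whole gene, and reads come from the 3′ end of transcripts.

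The depth gives narrow counting intervals for abundant genes. It limits statements on genes with a few UMIs per library, such as most taste receptor genes, where a count of 0 allows up to 3 UMIs.

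The calculations were tested on simulated counts drawn from 1 mean per gene, pooled over both libraries, for 16031 genes of the whole-library comparison, with 200 genes changed. Of the unchanged genes, 95.1% had intervals that held the true ratio. The right sign with an interval that excluded 0 was found for 100% of genes at log2 1, 94% at -1, 100% at 2 and 100% at -2. Of 40 unchanged lists, 0 fell outside the central 95% of random lists, and 40 of 40 lists raised 1.5-fold were found above it. The unchanged genes differed by counting error only and list genes were drawn independently. These rates therefore check the calculation and do not carry over to real lists. With 20 simulated cells that carried all markers, co-detection observed 24 cells against 8.86 expected, and 4 against 3.28 without them. Alternatives covered scaling, cell filters, UMI and CPM minimums, clustering settings, thinning and marker rules. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, anndata 0.12.19 and matplotlib 3.10.9.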

Results

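Single-cell RNA sequencing was used to compare mouse taste organoids kept in 2 culture formats. The organoids, epithelial cultures grown from the papillae of the adult C57BL/6 mouse tongue, were either embedded in Matrigel, a basement-membrane gel, or kept in suspension in low-attachment plates without the gel. Each format gave 1 droplet library, so no difference below has a replicate check, and every interval covers counting error only. The Matrigel library held 10041 cell barcodes with 122214067 unique molecular identifiers (UMIs, each a counted RNA molecule), and the suspension library held 12030 barcodes with 128439347. After filtering, 10040 and 12030 cells remained, with medians of 10382 and 8651 UMIs and of 3100 and 3008 genes per cell. Mitochondrial transcripts made up 1.95% and 2.09% of the UMIs, and ribosomal protein genes 20.5% and 19.9%.

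The first comparison asked which genes differed between the formats over all cells of each library. Among named genes with at least 50 CPM in 1 library and found in at least 5% of its cells, Dcpp3 and Dcpp1, salivary demilune cell secretory proteins, had the largest ratios towards suspension. They stood at 304.3 and 290.9 CPM (counts scaled to the same library total) in suspension against 13.04 and 12.55 in Matrigel, a log2 ratio of 4.54 for each (95% counting intervals 4.47 to 4.62 and 4.46 to 4.61). Sprr2d, a small proline-rich protein of the cornified envelope, had the largest one towards Matrigel, at 395.6 CPM in Matrigel and 20.1 in suspension (log2 -4.30, -4.36 to -4.24). Psca, a lipid-anchored surface protein, was at 2972 and 225 CPM (log2 -3.72, -3.74 to -3.71).

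Beyond these, the suspension library had more of Scgb3a1, a secreted secretoglobin (20.5 to 123.9 CPM, log2 2.60), Dmbt1, a secreted scavenger-receptor glycoprotein (22.5 to 112.3, log2 2.32), and the iron carrier Trf (23.8 to 110.2, log2 2.21). Kcne3, a potassium channel subunit, had a log2 ratio of 2.34, and Cyp2f2, a cytochrome P450 abundant in airway club cells, went from 317 to 1282 CPM (log2 2.02). Ptprd, Rgs4, Mslnl and Upk3a were also among the 12 highest ratios, at log2 2.21, 2.15, 2.14 and 1.92. Dcpp3 and Dcpp1 lie on chromosome 17, from 23917458 to 23919441 and from 23880876 to 23882853 (mm10). They are near-identical neighbours whose reads the counting could have split between them, so their separate levels are uncertain.

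In the other direction, the Matrigel library had more of Fxyd4, a regulator of the sodium pump (104 against 6.80 CPM, log2 -3.93), Stmn2, a microtubule-destabilizing protein best known from neurons (120.2 against 8.03, log2 -3.90), and Nccrp1 (60.3 against 4.24, log2 -3.83). Sprr2d, Psca and Nccrp1 are leading genes of the cornifying-like cluster, whose smaller share in suspension is given with the third comparison. The arginine-degrading enzyme Arg1 was at 659 and 75.6 CPM (log2 -3.12). Id3, an inhibitor of helix-loop-helix transcription factors and a textbook target of BMP signalling, was at 99.2 and 11.6 CPM (log2 -3.10, -3.18 to -3.02). Calml3, a calmodulin-like protein of stratified epithelia, was at 658 and 102 CPM (log2 -2.69), and Ndufa4l2, a mitochondrial protein induced by hypoxia, at 1625 and 260.5 CPM (log2 -2.64, -2.66 to -2.62). Bbox1, Mall and Prss27 completed the 12 lowest, at log2 -2.83, -2.73 and -2.69. Sprr2d lies on chromosome 3 from 92339140 to 92340873, Psca on chromosome 15 from 74714839 to 74717069, and Id3 on chromosome 4 from 136143497 to 136145755.

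The most abundant transcripts were largely shared. The nuclear RNA Malat1 led both libraries (24950 and 23215 CPM). Krt14, the keratin of basal stratified epithelium, was the second most abundant in Matrigel at 12841 CPM and stood at 5299 CPM in suspension (log2 -1.28). Wfdc18 and Wfdc2, whey-acidic-protein family members, had log2 ratios of 0.64 and 0.70 towards suspension. Ly6d was at 9341 and 5835 CPM. Among mitochondrial transcripts, mt-Rnr2 had a log2 ratio of -0.95 and mt-Cytb one of 0.69. S100a6, Tpt1 and Eef1a1 lay between -0.18 and -0.07, and Gm42418, a ribosomal RNA-derived gene model, at -0.10, which turned to 0.13 when each cell weighed the same. Rpl41, at 0.15, turned to -0.02 with trimmed-mean and with median-of-ratios factors. The median log2 ratio of the 16031 genes with enough UMIs was 0.19 by CPM. The trimmed-mean and median-of-ratios scalings moved it by -0.17 and -0.18, so a small positive ratio by CPM may only be this shift. Random lists matched to abundant genes had lower medians, such as 0.05 for immediate early and 0.06 for oxidative phosphorylation genes. Signs and 1.5-fold counts in this text are taken against 0.

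The second comparison asked which of 28 fixed gene groups stood apart as a whole. Each median was set against 10000 random lists of equal size and matched expression, as a description of these 2 libraries. The hypoxia and glycolysis group was lower in suspension, with 17 of its 23 members at least 1.5-fold lower, 0 at least 1.5-fold higher and a median log2 ratio of -0.95 (percentile 0). The glucose transporter Slc2a1 (155 against 54.0 CPM, log2 -1.52), the mitophagy gene Bnip3 (-1.39), Ndrg1 (-1.34) and the oxidoreductase Ero1l (-1.25) had its largest ratios. Nuclear genes of oxidative phosphorylation stayed within the random range (median 0.14, percentile 84.4), with 0 of 17 members apart by 1.5-fold.

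Structural genes of squamous epithelium were lower in the suspension library as a whole. Of 17 measured desmosome and cornified envelope genes, 10 were at least 1.5-fold lower and 0 higher (median -0.88, percentile 0), among them the transglutaminases Tgm3 (-3.36) and Tgm1 (-1.94), cornifelin Cnfn (-2.32) and desmoglein Dsg3 (-1.28). Among squamous keratins, 7 of 13 were lower and 3 higher (median -0.75, percentile 0). Krt6b and Krt16 had log2 ratios of -2.61 and -2.22, whereas Krt15 and Krt4 went the other way, at 1.64 and 1.34. Simple epithelial keratins had a median of 0.45 (percentile 99.6): Krt19 was at 471 and 1006 CPM (log2 1.09), Krt18 at 0.84 and Krt8 at 0.68, while Krt7 was at 1129 and 446 CPM (-1.34).

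Transcription factors of the taste lineage were higher in suspension, with 6 of 12 measured members at least 1.5-fold higher and 0 lower (median 0.62, percentile 99.9). The forkhead factors Foxa1 (17.8 against 50.7 CPM, log2 1.51) and Foxa2 (1.27) and Etv1 (0.97) were among those higher. Wnt targets had a median of 0.43 (percentile 98.4), with 6 of 14 higher and 2 lower. The negative-feedback gene Axin2 (1.62), the stem-cell receptors Lgr5 (5.25 against 14.8 CPM) and Lgr6 (0.76) and the ubiquitin ligase Znrf3 (0.68) were among those higher. Taste transduction genes did not stand apart (median 0.15 over 14 measured genes, percentile 35.2).

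S phase genes had a median of 0.44 (percentile 99.8), with Uhrf1 at 0.70 and Mcm2 at 0.69, whereas G2M and mitosis genes lay in the middle of the random lists (0.17, percentile 49.99). The p53 and apoptosis group had a median of 0.54 (percentile 99.99), with 7 of 14 members higher, among them Fas (0.98) and Bax (0.81). Immediate early genes had a median of 0.41 (percentile 99.98), with Egr1 at 127 and 296 CPM and Fos at 465.7 and 971 CPM. The interferon group was lower (median -0.43, percentile 0), with Isg15 at -1.56 and Irf7 at -1.34, although the antigen-presentation gene H2-K1 had a ratio of 0.42. That median turned to 0.14 (percentile 35.5) when members needed 200 UMIs instead of 50. Growth-factor ligands and feedback genes of EGFR signalling (median -0.16, percentile 0.14), Hedgehog genes (-0.25, percentile 1.42) and cholesterol synthesis genes (-0.04, percentile 1.29) also fell below the range of random lists. Hedgehog genes left the lower tail with other UMI minimums (percentiles 10.2 and 12.9).

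In all, 7 groups lay below the central 95% of random lists, 6 above it and 15 within. These values are for whole libraries, and many groups went other ways inside single classes and clusters, as given with the fourth comparison. Several of the 15 held members that went opposite ways. In the unfolded protein response group (median 0.15, percentile 63.2), the secretory-cell regulator Xbp1 was at 199.8 and 508 CPM (log2 1.34) while the stress factor Ddit3 was at -0.54. Among YAP targets (0.26, percentile 84.8), Cyr61 was at 1.02 and Ctgf at -1.50. Among Notch pathway genes (0.03, percentile 6.85), Hey1 was at 1.53 and the ligand Jag1 at -0.88. NRF2 targets (0.16, percentile 67.6) held Cbr3 at 1.08 and Nqo1 at -1.16. The heat shock (0.17, percentile 83.9), tight junction (0.23, percentile 85.1), integrin adhesion (0.17, percentile 77.4), metallothionein (0.15, percentile 65.0) and sex-linked (0.34, percentile 85.6) groups also stayed within the random range.

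**Figure D1:**
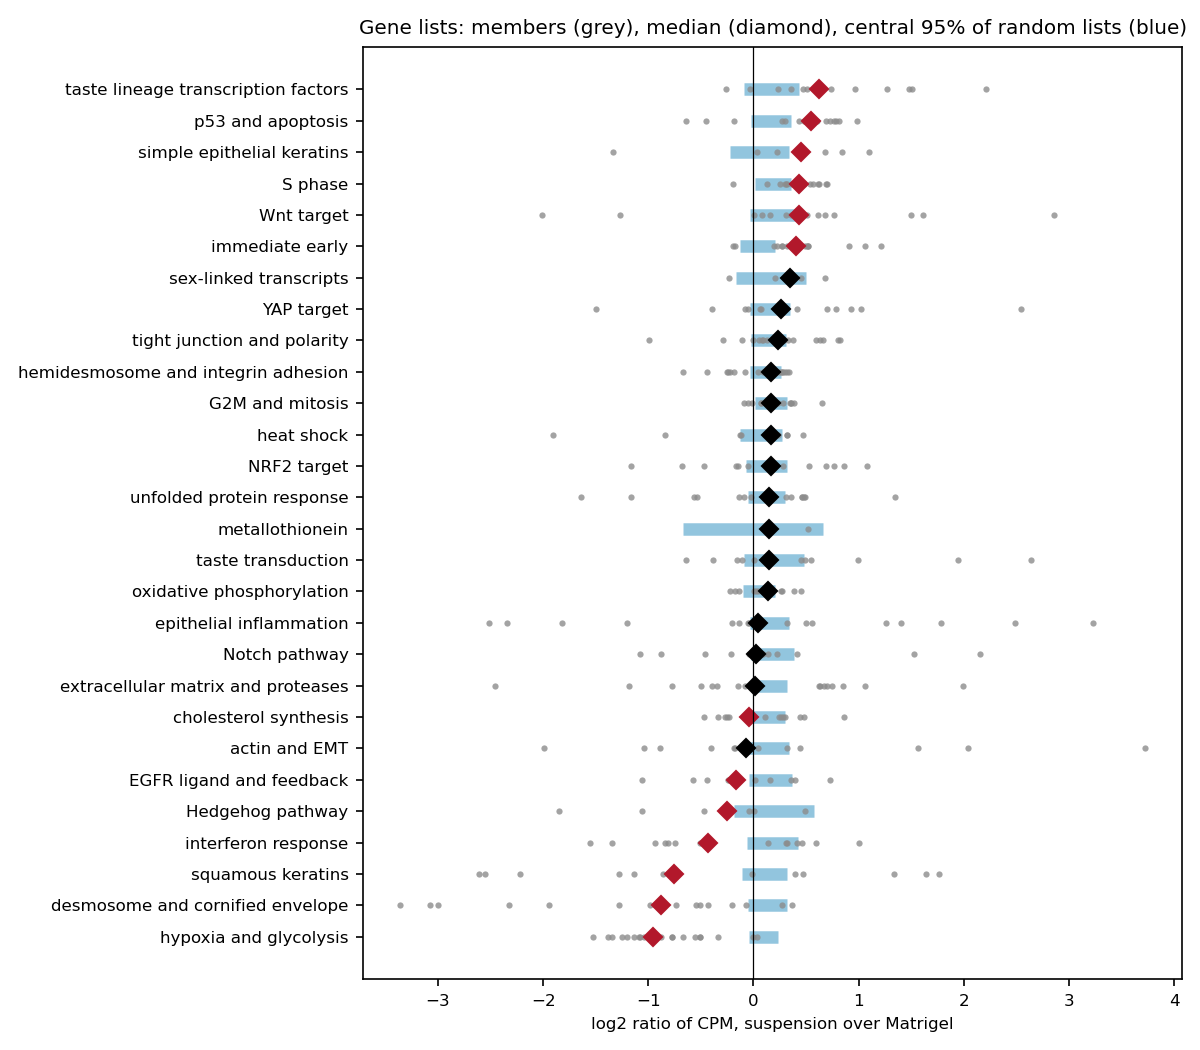
Log2 ratio of CPM, suspension over Matrigel, for the measured members (grey points) and the median (diamond) of each of 28 gene groups; blue bars span the central 95% of 10000 matched random lists, and red diamonds lie outside them. The hypoxia and glycolysis median lies lowest at -0.95 and the taste lineage transcription factor median highest at 0.62.

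The third comparison asked how cell classes were shared between the formats. Clustering gave 14 clusters, of which 9 fell into 5 named classes. Cornifying keratinocyte-like cells were 6.66% of Matrigel cells (6.18 to 7.17) and 0.441% of suspension cells (0.330 to 0.576). Suprabasal keratinocyte-like cells were 13.6% and 5.67%, and basal keratinocyte-like cells 37.8% and 27.3%. Cycling-like cells were 10.4% and 13.1%, and minor salivary gland-like cells 2.67% and 3.83%. The genes that part many of these clusters themselves differed between the libraries, so the cells were also clustered without genes that differed 2-fold or more. The shares were then 3.96% and 0.407% for cornifying, 29.1% and 9.18% for suprabasal, 19.96% and 21.8% for basal, 14.1% and 19.3% for cycling and 2.45% and 3.64% for gland-like cells. The order of the basal shares thus reversed, and the other 4 kept theirs. The suprabasal order reversed at a lower clustering resolution and the cycling order with fewer variable genes. With another clustering seed the cycling shares were nearly even, at 13.3% and 13.4%.

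Different clusters held most of a class in each library. Basal-like cells fell mainly in clusters 5 and 7 in Matrigel (23.6% and 11.3% of cells) and in cluster 8 in suspension (22.2%). Of the 10 leading genes, 1 was a basal marker in cluster 5 and 0 in clusters 7 and 8, so this name rests on other raised markers. Cycling-like cells fell mainly in cluster 12 in Matrigel (7.93%) and cluster 11 in suspension (10.8%), and suprabasal-like cells in cluster 2 (11.2%) and cluster 0 (5.59%). A cluster mostly from 1 library may be that library rather than a cell type: 99.2% of cluster 2, 92.7% of cluster 1 and 92.5% of cluster 5 came from Matrigel. Clusters 3, 4, 9, 10 and 13 stayed unnamed, with 11.3%, 8.73%, 5.50%, 2.82% and 0.568% of Matrigel cells and 1.57%, 9.54%, 25.4%, 7.12% and 6.01% of suspension cells. Cluster 9 expressed simple keratins (Krt8, Krt18, Krt19) with Gp2, Msln and Agr2 as leading genes. Cluster 4 was led by Cxcl14, Dcn and Smoc2 and had raised Lgr5, Lgr6 and Sox2. It scored best for taste progenitor and precursor, a name dropped for the same reason. Clusters 10 and 13 were shallow, with median depths of 1557 and 1604 UMIs and of 978 and 3302 UMIs in Matrigel and suspension.

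**Figure D2:**
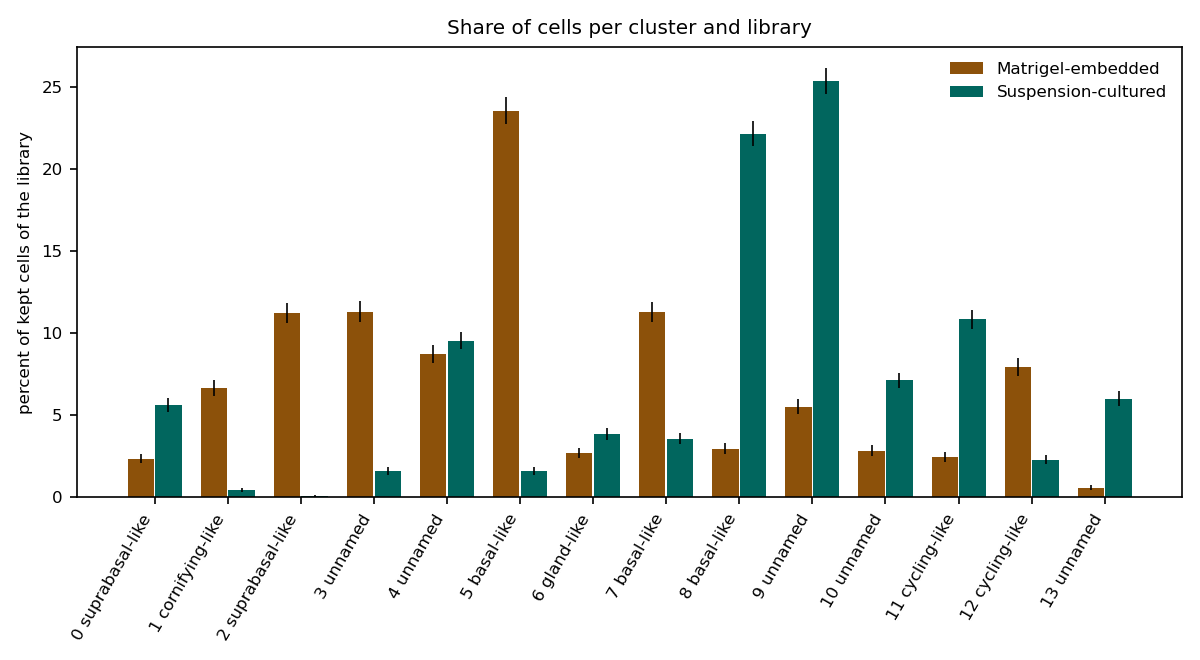
Share of kept cells (percent, vertical axis) in each of the 14 clusters (horizontal axis) in the Matrigel-embedded (brown) and suspension-cultured (green) library; error bars are exact 95% binomial intervals for counting error only. Cluster 5 holds 23.6% of Matrigel cells and cluster 9 holds 25.4% of suspension cells.

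The fourth comparison looked at expression inside the 5 named classes and the 5 unnamed clusters. The hypoxia and glycolysis group was lower in suspension in each of these 10 units, from a median of -1.32 in suprabasal-like cells and -1.31 in cornifying-like cells to -0.27 in gland-like cells and -0.19 in cluster 9, and it lay at or under the 2.5th percentile of random lists in all 10. Ndufa4l2 was at 2008 and 596 CPM in basal-like cells (log2 -1.75), at 1501 and 184 in cycling-like cells (-3.03) and at 496 and 54.0 in gland-like cells (-3.20).

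No other group lay outside the random lists on 1 side in all 10 units. Desmosome and cornified envelope genes lay below them in 6 units and above in 0, with medians from -0.72 in basal-like to 0.10 in cornifying-like cells. Squamous keratins lay below in 6 and above in 1, from -1.38 in gland-like to 0.66 in cornifying-like cells. Interferon genes (4 units), EGFR ligands and feedback genes (3 units) and Hedgehog genes (2 of 8 units with enough members) lay below and in no unit above. Taste lineage transcription factors lay above in 5 units and below in 0, from -0.12 in cluster 9 to 1.02 in cycling-like cells. The 5 were suprabasal-, basal- and cycling-like cells, the shallow cluster 10 (0.75) and cluster 4 (0.40). For every group, values in suprabasal-, basal- and cycling-like cells compare mainly different clusters. They do not show a change inside 1 cell type. The p53 and apoptosis genes likewise lay above in 5 and below in 0 (-0.08 in cluster 4 to 0.51 in suprabasal-like cells).

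Other groups lay outside on both sides. S phase genes lay above in 5 units and below in 1 (-0.32 in cluster 4 to 1.18 in suprabasal-like cells), and G2M and mitosis genes above in 2 and below in 3 (-1.05 in cluster 4 to 2.32 in suprabasal-like cells). Simple epithelial keratins lay above in 4 and below in 3 (-0.87 in cluster 4 to 1.25 in suprabasal-like cells), immediate early genes above in 3 and below in 4 (-0.51 in cluster 10 to 0.55 in gland-like cells) and cholesterol synthesis genes above in 3 and below in 1 (-0.34 in cluster 10 to 0.58 in basal-like cells). Wnt targets lay above in 1 of 9 units, basal-like cells (1.03), and below in 1, cluster 9 (-0.17). Of groups within the range over the whole library, integrin adhesion genes lay above in 4 and below in 1 (-1.14 in cluster 10 to 0.43 in cluster 3), unfolded protein response genes above in 2 and below in 4, tight junction genes above in 1 and below in 2, and NRF2 targets above in 1 and below in 2. YAP targets and heat shock genes each lay above in 2 and below in 1, and Notch pathway genes below in 2 of 9 and above in 0. Metallothioneins had enough members in 1 unit, cornifying-like cells, and lay above there (1.07). Oxidative phosphorylation, taste transduction and sex-linked genes lay within the range in all units compared (10, 9 and 9).

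In basal-like cells (clusters 5 and 7 in Matrigel, cluster 8 in suspension), the highest ratios included those of Cyp2f2 (73.2 against 776 CPM, log2 3.41), the alarmin Il33 (15.6 against 162, 3.37), the chemokine Ccl20 (3.33) and Krt15 (30.4 against 274, 3.17). Arg1 (85.3 against 6.45, -3.73), Psca (-3.53), Cwh43 (-3.15) and Stmn2 (-2.67) were among the lowest. In cycling-like cells (cluster 12 in Matrigel, cluster 11 in suspension), Dcpp3 (2.34 against 220 CPM), Scgb3a1 (11.01 against 150.3) and Trf (12.3 against 112) were among the highest, and Psca, Id3 and Dcn among the lowest (-3.94, -3.77 and -2.88). In suprabasal-like cells (cluster 2 in Matrigel, cluster 0 in suspension), Scgb3a1 (1.69 against 59.7 CPM), Acta2 (2.35 against 65.4) and Rgs4 (5.48 against 74.4) were among the highest, and Bbox1 (55.0 against 2.14) and Ndufa4l2 (2106 against 169.8) among the lowest.

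In gland-like cells, osteopontin Spp1 (4.48 against 193 CPM, log2 5.43), the water channel Aqp5 (24.6 against 255.7, 3.38) and Chst2 (8.40 against 73.3, 3.13) were higher, and Lgals7 (301.2 against 41.6, -2.86) and Sprr1a (784 against 156, -2.33) lower. In cornifying-like cells, of which suspension had 53, the keratin Krt75 (1.501 against 307 CPM) and the late envelope gene Lce3a (14.5 against 1918) were highest. Inside cluster 9, Cyp1b1 (1.73), Clu (1.58) and Nkd2 (1.28) were highest, and Id3 (195 against 12.9 CPM, -3.93), Ces1f (-3.40) and Id1 (-3.10) lowest. Krt15 and Pax1, followed across units after their values were seen, had log2 ratios of -0.63 and 0.14 there, against 3.17 and 2.78 in basal-like cells. Psca, which leads the cornifying cluster, was also counted at 84.9 and 2.72 CPM in cluster 4 and at 69.5 and 5.99 in basal-like cells, and free RNA was not excluded as the origin of those counts. Nor was it excluded for Lgals7, Sprr1a and the squamous keratins in gland-like cells. Sprr1a lay there below its whole-library level in both libraries (1701 CPM in Matrigel and 602 in suspension).

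**Figure D3:**
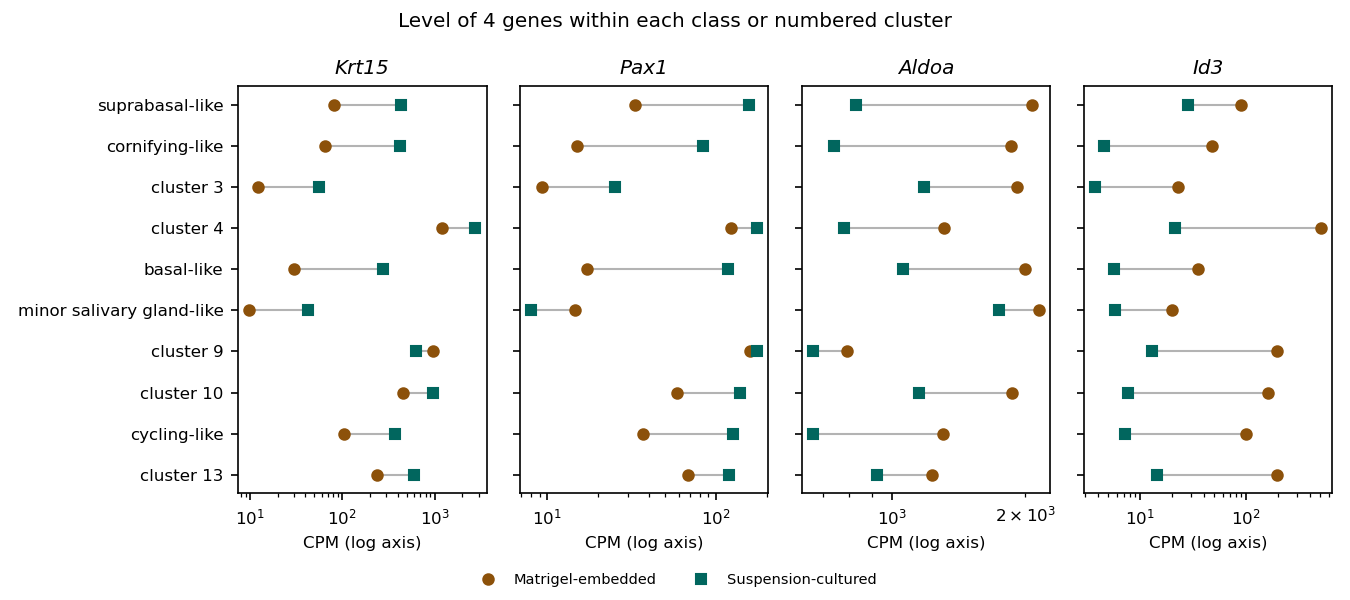
CPM (log axis) of Krt15, Pax1, Aldoa and Id3 in each named class or numbered cluster (vertical axis) in the Matrigel-embedded (circles) and suspension-cultured (squares) library; Krt15, Pax1 and Aldoa, a glycolytic enzyme, were chosen for it after their values were seen. In cluster 9, Pax1 stands at 158 and 175 CPM, while Id3 stands at 195 and 12.9 CPM.

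The fifth comparison asked whether taste receptor cell markers were present. Most were close to 0 in both formats. After each cell was thinned to 3000 UMIs, which kept 9180 Matrigel and 10247 suspension cells and left out 860 and 1783, 9 of 32 markers of type I, II and III taste cells were seen in at least 1% of the cells of either library. The channel genes Calhm1 and Calhm3 and the signalling regulator Rgs21 had 0 UMIs in both libraries, which allows up to 0.0327% and 0.0293% of thinned cells with a UMI. The transduction channel Trpm5 had 4 and 6 UMIs in all cells, the phospholipase Plcb2 13 and 12, the taste G protein Gnat3 37 and 35, and the sweet and umami receptor subunits Tas1r1, Tas1r2 and Tas1r3 5, 0 and 26 in Matrigel and 18, 3 and 40 in suspension. Pou2f3, the master regulator of type II cells, was at 0.393 and 0.327 CPM.

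Gng13, a G protein subunit of type II cells, had UMIs in 0.708% (0.547 to 0.902) of thinned Matrigel cells and 2.39% (2.10 to 2.71) of thinned suspension cells, or 1.63% and 5.84% without thinning, and its level was 1.98 and 7.62 CPM. Its shares were highest in cluster 9, at 5.97% and 5.58% of thinned cells (31 and 161 cells), and stood at 2.29% and 2.19% in cluster 4 and, in suspension, at 2.89% in cluster 13 and 1.86% in cluster 11. In basal-like cluster 5, taken as the background, they were 0.221% and 0.571%, and in basal-like cluster 8 of suspension 0.371% (median depths 8824 and 9734.5 UMIs in cluster 9, 9927.5 and 8458 in cluster 5). Otop1, the proton channel of sour-sensing type III cells, was in 0.599% (0.452 to 0.779) and 1.24% (1.03 to 1.47) of thinned cells, or 1.58% and 3.46% without thinning. Its shares were 3.26% and 3.53% in cluster 4 (27 and 37 cells, median depths 10535.5 and 7743.5 UMIs) and 2.505% and 2.08% in cluster 9 (13 and 60 cells). In cycling-like cluster 11 they were 2.05% and 1.01% (5 and 13 cells), and in suprabasal-like cluster 0 1.80% and 0.305% (4 and 2 cells). In cluster 5 they were 0.0885% and 0 of 175 cells, which allows up to 2.09%, so for suspension cluster 8 is the closer background (10 of 2425 cells, 0.412%). Ncam1 was at 14.4 and 35.0 CPM (log2 1.28) and Stmn2 at 120.2 and 8.03, both also listed as type III markers, yet both were also found in basal-like cells. Of type I markers, Slc1a3 was at 9.55 and 14.6 CPM (log2 0.61), and Entpd2 at 10.4 and 11.6 (0.16, which turned to -0.01 with trimmed-mean and median-of-ratios factors). General taste bud markers that other epithelia share were higher for Krt19, Krt18 and Krt8, as above, and for Cldn7 (0.59) and Hes6 (0.74), while Epcam (0.13, turning to -0.04 with both of those factors) and Ezr (0.08, turning to -0.09 and -0.10) were close to even. Of progenitor markers, Sox2 was at 131 and 186 CPM (0.51) and Shh at 1.203 and 0.335 (-1.85).

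The number of cells with at least 2 markers of 1 taste cell type was near that expected from independent detection, with all markers counted and cells thinned. At least 2 type II markers were seen in 90 thinned Matrigel cells with 87.9 expected and in 81 suspension cells with 87.7 expected. For type III the counts were 161 with 158.7 expected and 200 with 221 expected, and for type I 8 with 8.53 and 17 with 15.3. Cells with at least 3 markers were few but exceeded the expected number, 5.26-fold in Matrigel and 3.53-fold in suspension for type II (6 and 5 cells) and 1.21-fold and 2.45-fold for type III (5 and 14 cells). When Ncam1, Stmn2 and Dpysl3, each in over 5% of thinned cells, were left out after the data were seen, 4 Matrigel cells with 0.170 expected and 10 suspension cells with 0.982 expected had at least 2 of the other 9 type III markers, which is 0.0436% (0.0119 to 0.112) and 0.0976% (0.0468 to 0.179) of cells. Without Itpr3, the type II counts were 10 with 7.12 expected and 11 with 9.53 expected.

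The last comparison concerned the cell cycle. Thinned cells with UMIs of at least 3 G2M and mitosis genes were 11.1% (10.4 to 11.7) of the Matrigel library and 14.0% (13.3 to 14.6) of the suspension library, or 15.2% and 18.3% without thinning. Cells of this kind made up 91.8% and 76.2% of the cycling-like class but 0.706% and 1.29% of the basal-like class, which served as the background (median depths 15954 and 14920.5 UMIs, and 9036 and 8078). They were also 41.4% of the 415 thinned suspension cells of the unnamed cluster 13, and 0.157% and 3.61% of suprabasal-like cells. Summed S phase genes stood at 408 (404 to 411) and 525 (521 to 529) CPM, and summed G2M genes at 880 (875 to 885) and 989 (984 to 994) CPM. Mki67, the proliferation marker, was at 72.6 and 92.8 CPM (log2 0.36, 0.32 to 0.40).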

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

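The listing of genes that went opposite ways in different classes, by 4-fold or more each way and with at least 50 CPM in 1 library, was set up after the data were seen. Of 234 genes looked at over 8 classes and clusters, 3 met it, and no difference between classes was tested, since each culture has 1 library. Ppbp, a platelet-type chemokine, had a log2 ratio of 2.42 in suprabasal-like cells (289 CPM in Matrigel and 1548 in suspension) and of -2.92 in gland-like cells (332 and 43.9 CPM). Psca had a ratio of 2.21 in suprabasal-like cells (281 and 1302 CPM) and of -4.96 in cluster 4 (84.9 and 2.72 CPM). Tgm3, the epidermal transglutaminase, had a ratio of 3.50 in cornifying-like cells (9.44 and 107 CPM, the latter from 53 cells) and of -4.77 in suprabasal-like cells (58.4 and 2.14 CPM). Suprabasal-like cells were mostly cluster 2 in Matrigel and cluster 0 in suspension. Ppbp and Psca are among the leading genes of cornifying cluster 1, at 8211 and 36023 CPM over both libraries. Free RNA was not excluded as the origin of Psca counts in cluster 4 or of Ppbp counts in gland-like cells. Opposite regulation of these genes inside cell types is therefore not shown. Tgm3 is among those of cluster 0, at 63.7 CPM over both libraries. Cluster 0 holds 673 of the 682 suspension suprabasal-like cells, which stood at 2.14 CPM, so the change of cluster runs against the fall of Tgm3.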

How the results depend on the processing

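The alternatives chosen only after the data were seen are the removal of high doublet scores, leaving out clusters 10 and 13, a second clustering seed, clustering without differing genes, the 10 CPM naming floor and co-detection without broad markers. No paired analysis was possible because each culture has 1 library. Of 2156 log2 ratios (196 genes under 11 alternatives), 2145 kept their sign. Some of these alternatives changed the cells by at most 1 barcode, so their values could hardly move. They are no cell filter, at least 200 genes, at most 10% mitochondrial UMIs and called doublets kept. Under the trimmed-mean and the median-of-ratios factors, the log2 ratio of Entpd2 went to -0.0100 and -0.0130, Epcam to -0.040 and -0.042, Ezr to -0.092 and -0.095, Mt1 to -0.055 and -0.058, and Rpl41 to -0.021 and -0.024. This is the shift of all genes under those factors. Gm42418 went to 0.13 when each cell weighed the same, and the cause was not tested. Of the 24 genes chosen by size, 10 were shared with the choice at 10 CPM and 2 with no minimum, since more low genes then qualify. The 13 lists outside the random range stayed on their side under 9 of the 11 alternatives. With 10 UMIs needed per member 12 did, and with 200 UMIs 11 did, where the interferon median turned to 0.14 with fewer members. Of the 9, no cell filter, at most 10% mitochondrial UMIs and called doublets kept again changed the cells by at most 1 barcode. Weighing each cell the same put epithelial inflammation below the range (percentile 0.07), and 200 UMIs did so for actin and EMT genes (0.54).

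The share of basal-like cells turned higher in suspension at resolution 1.2 (log2 0.16), with called doublets kept (0.073) and without differing genes (0.13). In the other clusterings it stayed lower but varied widely, from -0.47 in the main run to -2.99 at resolution 0.4 (54.3% and 6.82%), and it was -0.16 with another seed. The suprabasal share turned to 0.89 at resolution 0.4, and the cycling share to -0.10 with 1000 variable genes. The cycling share was nearly even with another seed (log2 0.011), with high doublet scores removed (0.018) and with called doublets kept (0.048). It rose to 0.59 with cell cycle genes left out of the variable genes. The cause was not tested, but keeping the doublets adds 1 cell, so the basal order depends on small changes in the clustering. The cornifying-like share was lower and the gland-like share higher in suspension in each clustering run that had the class.

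Observed over expected co-detection was 5.26 in Matrigel and 3.53 in suspension for at least 3 type II markers (6 and 5 cells), and 1.21 and 2.45 for at least 3 type III markers (5 and 14 cells). For type I so few cells were expected that no value was given. Without broad markers it was 1.40 and 1.15 for type II and 23.5 and 10.2 for type III. Without thinning, values in Matrigel and suspension were 1.31 and 1.59 for type I (134 and 234 cells), 1.13 and 1.22 for type II and 1.13 and 1.10 for type III. The cause was not tested. The cell cycle shares in Matrigel and suspension were 15.2% and 18.3% without thinning, 13.5% and 16.9% for at least 2 genes, and 8.80% and 10.4% for at least 5, so the order held. Depth limits the taste markers, since many had under 50 UMIs in a library.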

Other observations

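The tests below were chosen after the result was seen, except the test of whether 2 populations of cells meet in dividing cells, whose bounds were written before.

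Epithelial inflammation genes went both ways. Over the whole libraries they did not stand apart as a group (median 0.05, percentile 13.3, with 5 of 17 at least 1.5-fold higher in suspension and 4 lower), but the median turned to -0.20 (percentile 0.07) when each cell weighed the same. Inside units the group lay above the random lists in 4 and below them in 3 of 10, and its median went from 1.08 in suprabasal-like cells (percentile 100) to -0.61 in cluster 9 and -1.13 in cluster 4 (percentile 0 in both). The epithelial cytokines Tslp (1.69 and 15.8 CPM, log2 3.23) and Csf2 (1.94 and 10.9 CPM, 2.49) were higher in suspension, while S100a9 (23.0 and 4.01 CPM, -2.52) and Il1a (18.96 and 3.75 CPM, -2.34) were higher in Matrigel. In suprabasal-like cells Tslp stood at 0.722 and 120.3 CPM, and cluster 0, which holds most of these cells in suspension, has it among its leading genes. Extracellular matrix and protease genes had a median of 0.01 (percentile 5.95), with 8 of 19 higher and 3 lower, but inside units they lay above the random lists in 4 and below in 1 (-0.91 in cluster 10 to 1.18 in suprabasal-like cells). Fibronectin Fn1 (1.07) and thrombospondin Thbs1 (0.85) were higher in suspension, and Tgfbi (-2.46) and the protease inhibitor Timp3 (-1.18) were lower.

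Actin and mesenchymal genes likewise split (median -0.07, percentile 3.81), and inside units they lay above the random lists in 3, suprabasal-like cells (0.69), cluster 3 (0.59) and cluster 9 (0.32), and below in 0. Acta2, smooth muscle actin, was at 11.9 and 48.9 CPM (log2 2.04) and Tagln at 1.57, while Vim was at 50.5 and 24.5 CPM (-1.04). Inside cluster 3, which holds 189 suspension cells, Acta2 stood at 45.6 and 591 CPM and Tagln at 35.4 and 460 CPM. Of markers of cells other than epithelium, some were low: Pecam1 of endothelium was in 0.240% and 0.293% of thinned cells, Ptprc of immune cells in 0.0218% of Matrigel and 0 of suspension cells, and Col3a1 of fibroblasts in 0 cells of both (a count of 0 allows 0.0327% and 0.0293%). These were picked after their values were seen, and others on the same lists were not low: Dcn and Vim, listed for fibroblasts, were in 5.28% and 4.51% and in 8.47% and 4.71% of thinned cells, and Acta2, listed for muscle, in 1.46% and 4.06%. Lyz2, an immune marker by its list, was at 179.8 and 302 CPM.

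The lower hypoxia and glycolysis genes in suspension held inside classes. A change in the shares of the clusters alone would leave the group near 0 inside single clusters. In units that are 1 cluster the group's median ran from -1.31 in cornifying-like cells to -0.19 in cluster 9, below the random lists in each. The median over all 10 classes and clusters was -0.72, but basal-like, suprabasal-like and cycling-like cells fell mainly in different clusters in each library. Makeup inside the units and free RNA were not tested. Scaling does not account for the lower group, since its highest median under 4 other scalings was -0.96. A lower hypoxic response of suspension organoids may be the biological reading, but with 1 library per culture the culture format cannot be told apart from any other difference between the libraries. Oxygen was not measured here, and handling before droplet capture is not described per library.

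Krt15, Pax1 and Foxa1, picked after their values were seen, were higher in suspension over the whole library (median log2 1.64). An effect of the library on all cells alike would raise them in any cluster. In the cluster that best matched cluster 9, clustered without differing genes, their median was 0.0717 (506 Matrigel and 2053 suspension cells). This argues only against an equal rise in all cells. The 1 cluster was chosen after Krt15 and Pax1 had been seen in cluster 9, where neither rose as in basal-like cells. Other clusters of that clustering were not tested. A hypothesis is that both cultures hold 2 populations, 1 with Krt15, Msln and Cyp2f2 and 1 with Stmn2, Vim and Bbox1, in other shares. Dividing suspension cells with at least 3 of 20 genes of each set numbered 254 against 331 expected, a ratio of 0.768 (0.684 to 0.858), between the bounds of 0.5 and 0.8 set beforehand. In Matrigel the ratio was 0.322 (0.236 to 0.427), where the sets were chosen, so whether suspension cells form separate populations or carry both programmes may not be settled from these libraries.

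Id1 and Id3, targets of BMP signalling, were lower in suspension (log2 -2.23 and -3.10). Free RNA from other cells would not put Id3 above the whole library, but in Matrigel cluster 4 its level was 5.07-fold that of the whole library (503 against 99.2 CPM). Other units lay below the whole library, such as gland-like cells (19.8 CPM) and basal-like cells (34.8 CPM), and free RNA was not excluded there. Shares of the clusters alone do not account for the fall of Id3 inside clusters 4 and 9 (-4.55 and -3.93), both above the whole library in Matrigel. Its smallest ratio over 10 classes and clusters was -1.65, in suprabasal-like cells, which fell mainly in different clusters in each library. Id1 fell less in cornifying-like cells (-0.68, -1.11 to -0.28), and a part of cell makeup in its fall was not tested. A weaker BMP response could lower both: of 8 other BMP-responsive genes, listed afterwards, 5 were measured, with a median of -0.75, and 3 of them were below -0.5 (Bambi -0.96, Id2 -0.76, Id4 -0.75), while Smad6 (0.08) and Smad7 (0.09) were not lower. That leaves a BMP difference open, and with 1 library per culture it cannot be told apart from a difference between the libraries.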
